A study of Mus musculus with 8 samples.

How the data were processed

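Poly(A) RNA was sequenced from immortalized mouse embryonic fibroblasts labelled as lacking the H3K9 methyltransferase genes Setdb1, Suv39h1, Suv39h2, Ehmt1 and Ehmt2, and the PRC1 gene Ring1b (Rnf2). The cells carried a control shRNA or an shRNA against Ring1a (gene symbol Ring1), delivered by lentivirus and selected with blasticidin. Each was grown without or with DS3201, an inhibitor of EZH1 and EZH2, at 1 uM for 7 days. The 4 groups had 2 libraries each, 8 libraries in all, and the groups were taken from the labels.

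The deposited table holds raw counts, whole numbers per gene symbol and per repeat subfamily, with no normalization applied by the authors. Reads were trimmed with Trim Galore and aligned with TopHat2 to mm10, per the submitters' processing notes, which give no versions. The counting tool, its rule for reads with several alignments, and the gene and repeat annotation are not given in the sources used here. The table had 25215 entries, 24062 genes and 1153 repeat subfamilies. Columns for the 8 libraries start with 20 or 28, and these prefixes are called set 20 and set 28 here. The labels number the replicates and give each number its own batch, but do not say which number belongs to which prefix. The other 8 columns match no labelled sample and were not used here.

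Whether the prefix pairs libraries across groups was checked before any calls were compared. Between groups, the differences of set 20 from set 28 correlated across genes with r from 0.559 to 0.897, so the prefix was used as the replicate block. The main fit, fixed in advance, had no term for the set. It therefore counts the difference between the sets as spread, and the block enters as an alternative fit.

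Total counts per library ran from 12738585 to 23688253. At these depths 3 counts, the floor used for genes with 0 counts, correspond to 0.127 to 0.236 CPM, the count scaled by library size. Floors and counting intervals (95% limits, exact binomial) cover counting error only, since reads without molecular identifiers are not independent molecules.

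Counts were tested in R 4.3.3 with edgeR 4.0.16. Low entries were removed with filterByExpr by group, which left 15287 entries, 14393 genes and 894 repeat subfamilies. Libraries were scaled by TMM. Log2 CPM values used a prior count of 2. A quasi-likelihood model with 1 term per group was fitted to all 8 libraries with the robust option. Each contrast was tested by a two-sided quasi-likelihood F test, with Benjamini-Hochberg adjustment over all entries tested and a threshold of 0.05. The contrasts were the knockdown without inhibitor, DS3201 with control shRNA, the knockdown plus DS3201 against control, the knockdown with inhibitor, DS3201 with the knockdown, and the interaction. Standard errors of log2 fold changes come from the fitted model. No standard error is given where a group held 0 counts.

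A gene with 0 counts in the lower group is given as at least N-fold higher, with 3 counts over that whole group as the floor. With 1 to 3 counts in the lower group, the ratio is given with its 95% counting interval.

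Gene lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists within a contrast, and again with the correlation estimated per list. Fry was run beside it. Lists with fewer than 5 tested members were given as values only. The lists were perturbed genes, PRC1 subunits, PRC2 subunits, Hox genes, developmental transcription factors, germline genes, the Rhox cluster, the protocadherin beta cluster, 2-cell embryo genes, imprinted genes, interferon-stimulated genes, cell-cycle genes, p53 targets and CDK inhibitors, senescence secretory genes, extracellular matrix and fibroblast genes, cholesterol synthesis genes, stress response genes, neuronal, muscle, epithelial, endothelial, and blood and macrophage markers, ribosomal protein genes, and cofactors of transposable element silencing. Repeat subfamilies were grouped by the family in the table and by names starting with IAP, and tested in the same way as a separate family of tests. Changes of the members were also adjusted over the list alone.

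The tests, gene lists, named-gene rule and most alternatives were fixed before the data were examined. Named genes were, per contrast, the perturbed genes, the 8 genes with the highest and the 8 with the lowest log2 fold change past the threshold, and up to 2 called members per list and direction. The ranked genes needed the same sign in both sets and at least 1 CPM in the higher group, and predicted models, clones and pseudogenes were left out. Where no gene passed, the 4 with the smallest p were named as not passing. Repeat subfamilies had their own rule, written after the table arrived and before any test: those past the threshold by the same ranking and a fixed set of well-known subfamilies. Where a member of a list is named because it passed with the replicate block, it was chosen after its values were seen. Gene positions are those of GENCODE M21 on GRCm38 (mm10).

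The alternatives were the replicate block, DESeq2 1.42.0, RLE size factors, the library total alone, no filter on low counts, at least 10 counts in 4 libraries, a fit to the compared libraries alone, an estimated correlation in the list tests, and each library left out in turn. Added after the data were seen were DESeq2 with the replicate block, the replicate block without the inhibitor library of set 28, the replicate block with an estimated correlation, and library sizes from genes alone. The scripts were tested on simulated data with known changes. With 2 libraries per group, the model without the block recovered 0% of simulated 2-fold changes, 14.9% to 26.9% of 4-fold changes and 65.2% to 74.2% of 16-fold changes in the 5 comparisons between groups. With the block these shares were 20.9% to 44.8%, 76.1% to 85.1% and 92.4% to 97.0%. Each simulation changed 67, 67 and 66 entries by these folds, which eases the adjusted threshold. Where fewer entries change, the shares recovered can be lower. Of 140 to 163 genes called per contrast with the block, 10 to 23 had not been changed in the simulation. For the interaction the shares recovered of 2-fold, 4-fold and 16-fold changes were 0%, 0% and 42.4% without and 4.48%, 53.7% and 84.8% with the block.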

Results

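RNA was sequenced from mouse embryonic fibroblasts labelled as lacking 5 H3K9 methyltransferase genes and Ring1b, in a 2 by 2 design. The control group carried a control shRNA, the knockdown group an shRNA against Ring1a (Ring1), the inhibitor group the control shRNA with DS3201, and the combined group the Ring1a shRNA with DS3201. Ring1 encodes the PRC1 ubiquitin ligase that remains when Ring1b is absent, and DS3201 inhibits the H3K27 methyltransferases EZH1 and EZH2. The series title names the joint role of H3K27me3 and the PRC1 pathway in silencing once H3K9 methylation is lost. Each group had 2 libraries (n = 2), 1 in set 20 and 1 in set 28. Total counts in set 20 and set 28 were 20554685 and 15345960 in the control and 23688253 and 14782753 in the knockdown. They were 16908517 and 12738585 in the inhibitor group and 15377902 and 15701329 in the combined group. The p-values measure only the spread between these libraries, which may be technical.

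Ring1 (chr17, 34020792 to 34024680) was lower in every library with the Ring1a shRNA than in its partner of the same set. Its level in set 20 and set 28 was 20.2 and 9.73 CPM in the control, 4.51 and 1.41 CPM in the knockdown, 20.4 and 7.50 CPM in the inhibitor group, and 3.51 and 2.04 CPM in the combined group. The log2 fold change of Ring1 was -2.32 ± 0.73 (SE) for the knockdown without inhibitor (-2.14 and -2.69 within the sets, adjusted p = 1). With inhibitor it was -2.33 ± 0.74 (-2.50 and -1.82, adjusted p = 1). With the replicate block the adjusted p values were 0.705 and 0.594. In the combined group against control it was -2.43 ± 0.73, and Ring1 fell in that comparison with the replicate block (adjusted p = 0.211 without and 0.00467 with it). The remaining 8 perturbed genes did not pass in any comparison. RNA of Rnf2 (Ring1b) was 28.9 and 50.5 CPM in the control and 31.4 and 89.0 CPM in the inhibitor group. RNA of the 5 methyltransferase genes was also present, with control means of 86.5 CPM for Suv39h1, 15.05 CPM for Suv39h2, 46.3 CPM for Ehmt1, 206 CPM for Ehmt2 and 7.68 CPM for Setdb1. The edited positions are not given, so these levels do not show whether the 6 genes are disrupted. Ezh2 was 59.6 and 89.9 CPM in the control and 80.9 and 155 CPM in the inhibitor group. As a list, the 9 perturbed genes did not pass in the knockdown (adjusted p = 0.234).

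**Figure D1:**
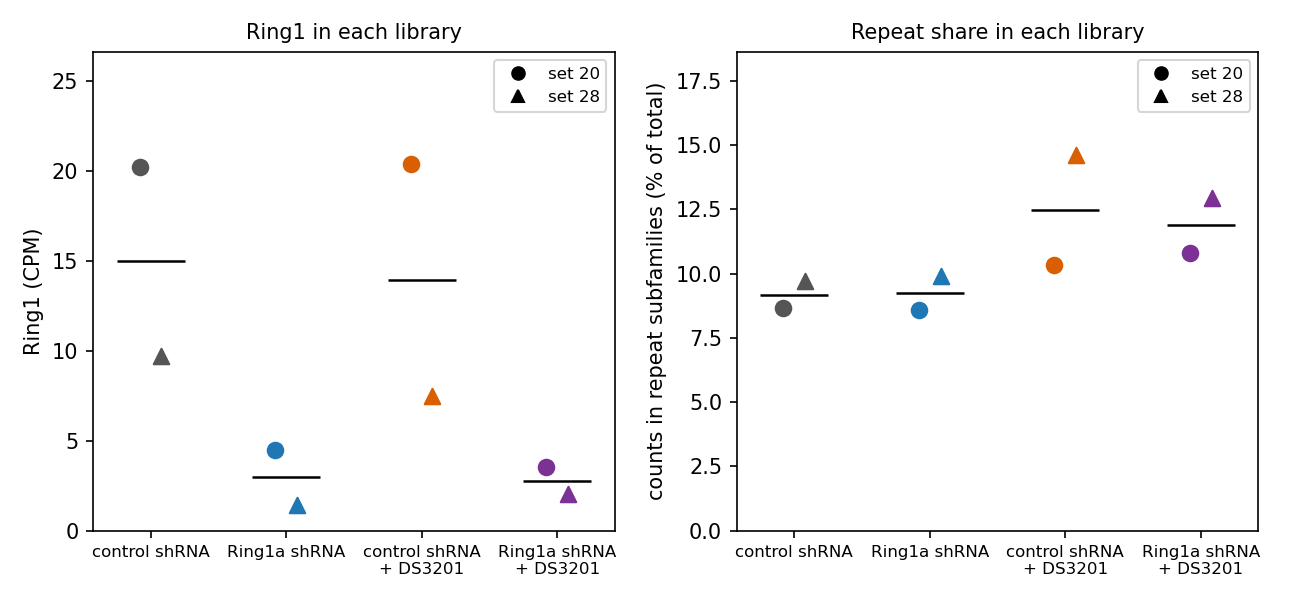
Level of Ring1 (CPM, left) and share of counts in repeat subfamilies (% of the total, right) by group, where each point is a library (circle set 20, triangle set 28) and each line the group mean. Ring1 was 1.41 to 4.51 CPM in the 4 libraries with the Ring1a shRNA and 7.50 to 20.4 CPM in the other libraries.

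The libraries differed along DS3201 and along the set. The first principal component held 54.4% of the variance and parted the 4 libraries with DS3201 from the 4 without it. The next held 29.3% and parted set 20 from set 28. The inhibitor library of set 28 stood apart on the following component (7.57% of the variance, at 52.8 where the other libraries lay from -30.4 to 26.7). Replicate libraries correlated across genes with r of 0.949 in the control, 0.947 in the knockdown, 0.913 in the inhibitor group and 0.947 in the combined group.

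**Figure D2:**
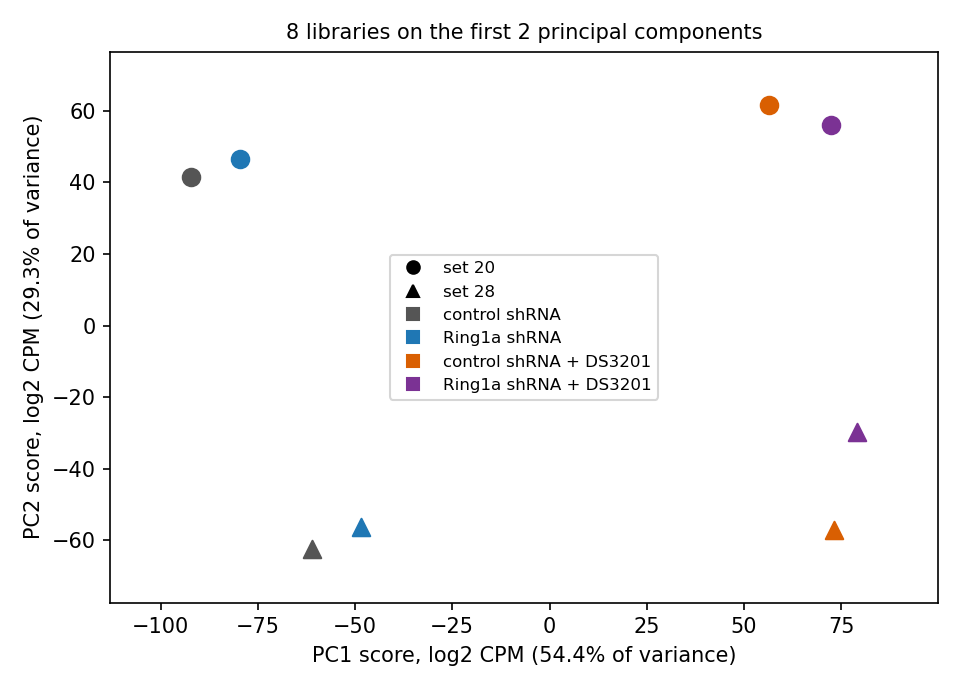
Principal components of log2 CPM of the 8 libraries, with the share of variance on each axis, colours for the 4 groups, circles for set 20 and triangles for set 28. Component 1 (54.4%) parted libraries with and without DS3201, and component 2 (29.3%) parted the sets.

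DS3201 with control shRNA, the comparison for EZH1 and EZH2 inhibition in cells that keep Ring1a, raised genes of which most were under 1 CPM in the control. Kctd12, an auxiliary subunit of GABA-B receptors (chr14, 102976581 to 102982637), rose from 0 counts in both control libraries to 28.9 and 51.4 CPM, at least 451-fold (adjusted p = 0.0222). Cyfip2, a component of the WAVE actin-regulating complex (chr11, 46193850 to 46312859), rose from 0 counts to 31.1 and 23.7 CPM, at least 338-fold (adjusted p = 0.0096). From 0 counts in the control, Heph, a copper-dependent ferroxidase (chrX, 96455359 to 96574485), rose at least 229-fold, Jakmip2 at least 172-fold and Ogfrl1 at least 169-fold (adjusted p = 0.0335, 0.0478 and 0.0136). Rgs2, a regulator of G protein signalling, rose at least 108-fold, Stox2 at least 103-fold and H2-Aa, an MHC class II chain (chr17, 34282744 to 34287823), at least 91.4-fold (adjusted p = 0.0103, 0.0479 and 0.0282). In all, 109 genes rose and 0 fell in the fit without the block, which counts the difference between the sets as spread. With the block 982 rose and 108 fell. All 109 were higher in both sets. Of these 109 genes, 97 were under 1 CPM in the control (89.0%), as were 2266 of all 14393 tested genes. The median level of the 109 went from 0.105 to 11.4 CPM. The share under 1 CPM is not a trait of the response alone, since the fit recovered 0% of simulated 2-fold and 19.4% of 4-fold changes. Genes at 0 counts in the control also passed the filter only through another group. With the block the share was 75.9% of 982 genes, so that 745 of the 2266 tested genes under 1 CPM rose. The list tests compare members with all tested entries, not with genes of similar level. In each comparison with DS3201, a list of genes that were low without it may therefore pass upward through this general rise. Counts of list members called are to be read beside these shares.

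Genes of the 2-cell embryo formed the group with the largest shift under DS3201. Of 25 tested members 11 rose and 0 fell, and 22 rose adjusted over the list alone. Zscan4b, of the family that marks 2-cell-like cells (chr7, 10900740 to 10905050), rose by 7.21 ± 0.51 log2 (adjusted p = 0.0096). Usp17ld, a deubiquitinase (chr7, 103249737 to 103252505), rose from 2 counts over the control, a ratio of 292 with a counting interval of 80.4 to 2420 (adjusted p = 0.00235). The median log2 fold change of the list was 7.05 (5.14 and 4.85 within the sets, and 5.37 with 9 members at 0 counts set to their bound). The list test gave adjusted p = 3.23e-58, and adjusted p = 0.00583 with an estimated correlation.

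Developmental transcription factors were also higher with DS3201: 2 of 76 tested members rose and 0 fell, and 13 rose and 1 fell adjusted over the list alone. Six2, a regulator of nephron progenitors (chr17, 85684277 to 85688274), rose by 5.54 ± 0.55 log2 (adjusted p = 0.0148). Alx4, a homeobox factor of limb and craniofacial patterning, rose from 2 counts over the control to 2.38 and 2.12 CPM, a ratio of 40.9 with a counting interval of 10.9 to 345 (adjusted p = 0.0439). With the replicate block 17 members rose, among them Eomes (2.57 ± 0.32, adjusted p = 0.0074), Irx3 (6.74 ± 1.32, adjusted p = 0.00795) and Gata2 (1.23 ± 0.21, adjusted p = 0.0187), and Twist2, a mesenchymal factor, fell (-0.93 ± 0.21, adjusted p = 0.0428). The list median was 0.47 (0.57 and 0.58 within the sets, adjusted p = 0.000338, and adjusted p = 0.212 with an estimated correlation). Of 27 tested Hox genes none passed (median 0.43, adjusted p = 0.417), and Hoxd11 rose with the block (adjusted p = 0.0331).

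Lists of neuronal, muscle, endothelial and blood markers and of imprinted genes also passed upward, tested against all entries and not against genes of similar level. With 1 library left out the endothelial, blood and muscle lists lost their call in at least 1 fit (adjusted p of up to 0.278, 0.174 and 0.0538). Uchl1, a neuronal deubiquitinase, rose by 5.67 ± 0.52 log2 (adjusted p = 0.0146). It was 1 of 16 neuronal markers, of which 5 rose adjusted over the list alone (median 1.23, adjusted p = 6.27e-06, and adjusted p = 0.0772 with an estimated correlation). Flt4, a receptor for lymphatic growth factors, rose by 7.39 ± 0.81 (adjusted p = 0.0184), 1 of 11 endothelial markers (median 0.72, adjusted p = 0.00381, and adjusted p = 0.212 with an estimated correlation). Lyz2, a lysozyme of macrophages, rose by 5.10 ± 0.71 (adjusted p = 0.0478). With H2-Aa it made 2 of 9 blood and macrophage markers that rose (median 0.45, adjusted p = 0.00508, and adjusted p = 0.127 with an estimated correlation). Of 18 muscle markers none passed and 5 rose adjusted over the list alone. With the block the embryonic myosin gene Myh3 rose by 6.48 ± 1.41 (list median 1.24, adjusted p = 0.00441, and adjusted p = 0.127 with an estimated correlation). Adjusted over the list alone, 3 endothelial and 3 blood and macrophage markers rose, and 2 of 13 epithelial markers, whose list test gave adjusted p = 0.212. Peg3, a paternally expressed zinc finger gene, rose by 8.48 ± 1.16 (adjusted p = 0.0425). It was 1 of 35 imprinted genes, of which 9 rose adjusted over the list alone (median 0.66, adjusted p = 0.00058, and adjusted p = 0.127 with an estimated correlation). With the block 8 imprinted genes rose, among them the growth factor gene Igf2 (3.58 ± 0.31, adjusted p = 0.00209) and Mest (2.87 ± 0.30, adjusted p = 0.0041).

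Germline genes (0 of 31 passing, 0 adjusted over the list alone) had a median of 1.07 (1.28 and 0.93 within the sets, adjusted p = 0.000787, and adjusted p = 0.127 with an estimated correlation). With the block 10 of them rose, among them Tex14, of germ cell bridges (4.24 ± 1.10, adjusted p = 0.0436), and Pgk2, the testis form of phosphoglycerate kinase (2.51 ± 0.46, adjusted p = 0.0248). Of all tested genes under 1 CPM in the control, 745 of 2266 rose with the block. The counts in this paragraph therefore do not by themselves set these lists apart from other genes of low level. The protocadherin beta cluster (0 of 13 passing, 2 adjusted over the list alone) had a median of 3.60 (3.24 with members at 0 counts set to their bound, adjusted p = 6.13e-06, and adjusted p = 0.212 with an estimated correlation), and 5 members, Pcdhb17 among them, rose with the block. The Rhox cluster had 1 tested member, Rhox5, at -0.74 ± 0.50 (adjusted p = 0.62), and was not tested as a list.

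Fibroblast and matrix genes moved in both directions. Fbln1, the matrix protein fibulin-1, rose by 5.72 ± 0.45 log2 (adjusted p = 0.0103). The list median was -0.26 and its mean 0.21 (50 members, 2 higher and 2 lower adjusted over the list alone, list test downward with adjusted p = 0.00631, and adjusted p = 0.127 with an estimated correlation). With the block 3 members rose, Fbln1, Dcn and Pdgfra, and 6 fell, among them the receptor gene Pdgfrb (-1.50 ± 0.21, adjusted p = 0.0106), smooth muscle actin Acta2 (-1.28 ± 0.18, adjusted p = 0.0107) and the collagen gene Col4a1 (-0.97 ± 0.19, adjusted p = 0.0296). Slc7a11, the cystine transporter, rose by 3.99 ± 0.51 (adjusted p = 0.0452), 1 of 28 stress response genes (list adjusted p = 0.85). Cholesterol synthesis genes had a median of -0.52 (-0.55 and -0.48 within the sets, 0 of 24 passing, adjusted p = 1.6e-05, and adjusted p = 0.374 with an estimated correlation).

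The remaining lists held no gene that passed with DS3201. Interferon-stimulated genes had a median of -0.38 (-0.06 in set 20 and -1.21 in set 28, adjusted p = 0.000696, and adjusted p = 0.69 with an estimated correlation). Without the inhibitor library of set 28 the direction turned with adjusted p = 0.268. Ribosomal protein genes had a median of -0.08 (0.15 and -0.31 within the sets, adjusted p = 0.047, adjusted p = 0.69 with an estimated correlation and up to 0.928 with 1 library left out). The p53 targets and CDK inhibitors (adjusted p = 0.417), senescence secretory genes (adjusted p = 0.144), cell-cycle genes (adjusted p = 0.85), PRC1 subunits (adjusted p = 0.513), PRC2 subunits (adjusted p = 0.417), silencing cofactors of transposable elements (adjusted p = 0.436) and perturbed genes (adjusted p = 0.436) did not pass as lists. Adjusted over the list alone, 5 senescence secretory genes, 1 PRC1 subunit and 1 silencing cofactor rose. With the block the p53 targets Cdkn1a, a CDK inhibitor (1.51 ± 0.25, adjusted p = 0.0173), and Pmaip1, a BH3-only death gene (2.42 ± 0.19, adjusted p = 0.00139), rose. So did the PRC1 genes Bmi1 (0.95 ± 0.17, adjusted p = 0.0227), Phc1 (0.71 ± 0.15, adjusted p = 0.0354) and Rybp (1.02 ± 0.17, adjusted p = 0.0187) and the DNA methyltransferase gene Dnmt3b (1.99 ± 0.25, adjusted p = 0.00734).

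The count of genes depended on the set difference and on the libraries fitted. In a fit to only the libraries compared, 0 genes passed. For the 0 genes that fell in edgeR, 325 were lower at an unadjusted p under 0.05, DESeq2 called 67 lower and 708 higher, and edgeR with the replicate block called 982 higher and 108 lower. With the block and without the inhibitor library of set 28, a fit added after the data were seen, 596 were higher and 154 lower. All 108 were lower in both sets, and their median went from 56.2 to 28.3 CPM. The count of 109 became 1 without the control library of set 20 (BB287469, picked after its values were seen) and 11 without that of set 28. It became 12 and 6 without the inhibitor libraries of sets 20 and 28, and 6 and 6 without the combined libraries.

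DS3201 with the Ring1a knockdown, the same inhibition in cells with lowered Ring1, raised 92 genes and lowered 0 without the block. With the block it raised 913 and lowered 126. From 0 counts in the knockdown, Sod3, an extracellular superoxide dismutase, rose at least 472-fold, Tmem47 at least 181-fold, H2-Aa at least 174-fold and Slc7a2, a cationic amino acid transporter, at least 140-fold (adjusted p = 0.0384, 0.0219, 0.0217 and 0.0242). Hectd2 rose at least 89.2-fold and Klhl13 at least 80.8-fold (adjusted p = 0.038 and 0.031). Kctd12 rose with a ratio of 2560 (counting interval 458 to 101000, adjusted p = 0.0196) and Cyfip2 with a ratio of 1420 (254 to 56100, adjusted p = 0.00805), each over 1 count in the knockdown libraries. Of the 92 genes, 79 were under 1 CPM in the knockdown (85.9%), as were 2085 of all 14393 tested genes. The median of the 92 went from 0.128 to 13.6 CPM. With the block 731 of those 2085 genes rose.

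The 12 lists that passed with DS3201 in the knockdown cells were all among the 13 that passed in the control cells. Of 25 2-cell embryo genes 11 rose and 24 rose adjusted over the list alone, with Usp17ld at 5.61 ± 0.29 and Usp17lb at 7.14 ± 0.50 (adjusted p = 0.0036 and 0.00748). The list median was 6.78 (4.83 and 5.19 within the sets, 5.61 at the bound), with adjusted p = 4.67e-69, and adjusted p = 0.00171 with an estimated correlation. Developmental factors had 2 of 76 members that rose, Six2 (6.13 ± 0.52, adjusted p = 0.0113) and Alx4 (at least 68.3-fold, adjusted p = 0.016), and 17 did adjusted over the list alone. The list median was 0.59 (list adjusted p = 1.44e-07, and adjusted p = 0.116 with an estimated correlation). Igf2 (4.17 ± 0.50, adjusted p = 0.04), Fbln1 (5.50 ± 0.42, adjusted p = 0.0109), Uchl1 (5.35 ± 0.45, adjusted p = 0.0138), Flt4 (6.08 ± 0.59, adjusted p = 0.0229) and Lyz2 (4.89 ± 0.65, adjusted p = 0.0485) rose. They were the called members of the imprinted, matrix, neuronal, endothelial and blood lists, the last with H2-Aa. These list tests gave adjusted p of 0.000901, 0.00558, 7.37e-06, 0.000543 and 0.000543, and adjusted p = 0.116, 0.102, 0.0781, 0.116 and 0.101 with an estimated correlation. Muscle markers (adjusted p = 0.000438), germline genes (adjusted p = 0.00179), the protocadherin beta cluster (adjusted p = 6.91e-06) and cholesterol synthesis genes (median -0.22, adjusted p = 0.0214) passed without a called member, with adjusted p = 0.101, 0.116, 0.189 and 0.639 with an estimated correlation. The cholesterol list lost its call with 1 library left out (adjusted p of up to 0.105). Adjusted over the list alone, 9 imprinted genes, 6 neuronal, 6 muscle, 3 blood and 2 endothelial markers, 2 protocadherin genes, 1 Hox gene and 1 stress response gene rose, and 1 matrix gene rose and 1 fell.

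Interferon-stimulated genes were lower with DS3201 in the knockdown cells. Their median was -1.06 (-0.75 in set 20 and -1.79 in set 28), 0 of 56 passed, and the list test gave adjusted p = 3.67e-14, and adjusted p = 0.463 with an estimated correlation. With the block 15 fell and 0 rose, among them Ifit3, an antiviral effector (-2.32 and -3.71 within the sets, adjusted p = 0.00654), and Irf7 (-2.03 ± 0.43, adjusted p = 0.0416). The lists of perturbed genes, PRC1, PRC2, Hox, cell-cycle, p53, senescence, stress, epithelial, ribosomal protein and silencing cofactor genes did not pass (adjusted p of 0.0822 or more). In the block, the matrix genes Postn (-1.69 ± 0.22, adjusted p = 0.00852) and Pdgfrb (-1.50 ± 0.21, adjusted p = 0.00975) fell.

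Genes that rose with DS3201 overlapped between the arms, which share no libraries. Both arms were tested in 1 fit with a common dispersion per gene, so their calls are not independent. Of the 109 and 92 genes, 83 rose in both, where 0.697 would be shared by independent draws from all tested genes. Such draws are no fair yardstick, since most genes called higher were under 1 CPM without DS3201. In the control only 2266 of the 14393 tested genes were. With the block 756 of 982 and 913 genes rose in both (62.3 by independent draws) and 47 of 108 and 126 fell in both (0.945). Across 14393 genes, which are not independent replicates, the log2 fold changes of DS3201 with and without the knockdown had Pearson's r of 0.934 and Spearman's rho of 0.729. Genes at 0 counts without DS3201 have large fitted values in both arms (Zfp352 at 10.09 with control shRNA and 10.17 with the knockdown). Pearson's r weighs such genes heavily, and both coefficients were lower with no filter on low counts, as given below. For the 0 genes that fell in edgeR with the knockdown, 216 were lower at an unadjusted p under 0.05, DESeq2 called 38 lower and 612 higher, and the replicate block gave 126 lower and 913 higher. A fit to only the libraries compared called 2 genes higher. The count of 92 became 1 without either knockdown library or the combined library of set 20, 8 without the combined library of set 28, and 7 without either inhibitor library. The gene left without the set 20 libraries and without the knockdown library of set 28 was BB287469, picked after its values were seen.

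**Figure D3:**
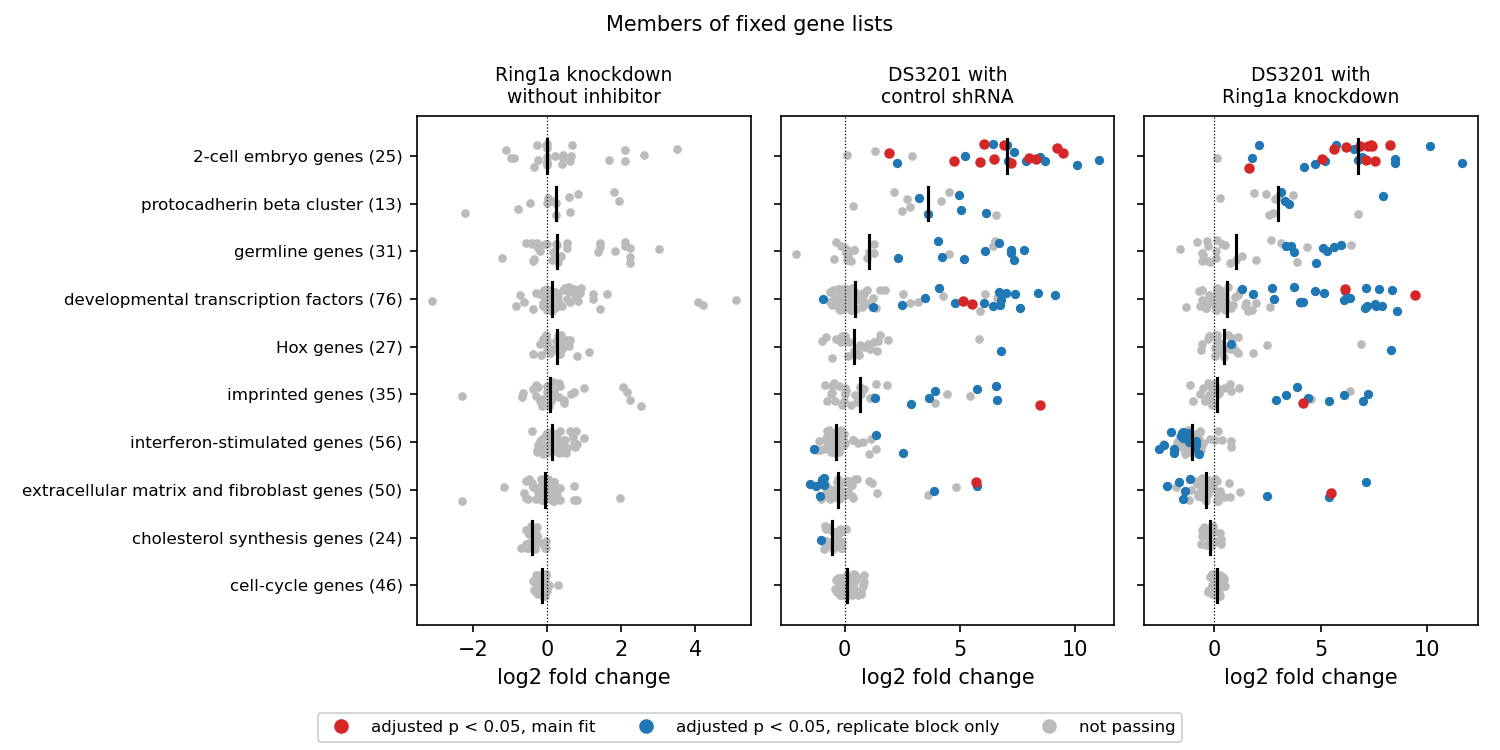
Log2 fold change of each tested member of 10 gene lists for the knockdown, DS3201 with control shRNA and DS3201 with the knockdown, with a black line at the list median; red points had adjusted p under 0.05 in edgeR, blue points with the replicate block alone, and grey points neither. The median of the 2-cell embryo genes was 0 in the knockdown and 7.05 and 6.78 with DS3201.

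The combined group against control, which shows both perturbations together, had 217 genes higher and 5 lower without the block. With the block 1377 were higher and 315 lower. From 0 counts in the control, Kctd12 rose at least 776-fold, Robo1, an axon guidance receptor, at least 638-fold, Cyfip2 at least 431-fold and Ogfrl1 at least 195-fold (adjusted p = 0.0162, 0.0453, 0.00752 and 0.0114). H2-Aa rose at least 158-fold, Heph at least 151-fold and Slc7a2 at least 127-fold (adjusted p = 0.0199, 0.0298 and 0.0208), and Tbc1d9 rose with a ratio of 1970 over 1 count in the control (counting interval 354 to 78000, adjusted p = 0.0136). The 5 genes that fell were Cd6 (-2.01 ± 0.32), the splicing factor gene Mbnl3 (-1.62 ± 0.25), Fah, of tyrosine breakdown (-1.53 ± 0.24), the ethanolamine kinase gene Etnk1 (-1.37 ± 0.21) and Xpo6, the nuclear exporter of actin (-1.23 ± 0.20), with adjusted p of 0.0476, 0.0437, 0.0461, 0.0429 and 0.0459. Of the 217 genes, 185 were under 1 CPM in the control (85.3%), as were 2266 of all 14393 tested genes. The median of the 217 went from 0.0908 to 9.75 CPM. With the block 997 of those 2266 genes rose.

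Of 76 developmental factors 6 rose in the combined group, and 19 adjusted over the list alone. They included Six2 (6.34 ± 0.55, adjusted p = 0.00951) and Gata2, of blood and endothelial progenitors (2.18 ± 0.24, adjusted p = 0.02). The list median was 0.82 (1.00 and 0.73 within the sets, adjusted p = 2e-09, and adjusted p = 0.094 with an estimated correlation). With the block 25 rose (adjusted p = 0.0407 with the block and an estimated correlation). Hox genes had a median of 0.48 (0.75 and 0.40, 0 of 27 passing, adjusted p = 0.0211, and adjusted p = 0.435 with an estimated correlation, and up to 0.32 with 1 library left out). With the block 5 rose, among them Hoxa5 (1.87 ± 0.41, adjusted p = 0.0308) and Hoxc9 (1.40 ± 0.30, adjusted p = 0.0293). Of 2-cell embryo genes 12 of 25 rose, 24 adjusted over the list alone, with Usp17ld at a ratio of 343 and Zscan4b at 6.92 ± 0.51 (adjusted p = 0.00199 and 0.00752). The list median was 6.92 (5.38 at the bound), with adjusted p = 2.65e-57, and adjusted p = 0.00368 with an estimated correlation. Pcdhb17 rose with a ratio of 38.1 (10.2 to 321, adjusted p = 0.0459), 1 of 13 protocadherin genes (list adjusted p = 9.7e-06, and adjusted p = 0.217 with an estimated correlation).

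Imprinted genes had 3 of 35 members that rose, among them Igf2 (4.49 ± 0.51, adjusted p = 0.0288) and Peg3 (8.66 ± 1.16, adjusted p = 0.0298), with list adjusted p = 0.000282, and adjusted p = 0.094 with an estimated correlation. Areg, an EGF receptor ligand (3.47 ± 0.54, adjusted p = 0.0459), Fbln1 (6.30 ± 0.45, adjusted p = 0.00806), Slc7a11 (3.79 ± 0.51, adjusted p = 0.0379) and Dnmt3b (2.36 ± 0.38, adjusted p = 0.0479) rose in the senescence, matrix, stress and silencing lists. The first 2 of these lists passed (adjusted p = 0.0248 and 0.00127, and adjusted p = 0.435 and 0.094 with an estimated correlation). The matrix list passed downward with a median of -0.49 and a mean of 0.05. Uchl1 (6.72 ± 0.52) and Dcx, of migrating neurons (at least 116-fold), rose among neuronal markers, Flt4 (8.29 ± 0.81) among endothelial markers, and Lyz2 (5.52 ± 0.70) with H2-Aa among blood markers (adjusted p = 0.00893, 0.0474, 0.0121 and 0.0299). Neuronal, muscle, endothelial, blood, epithelial and germline lists passed (adjusted p of 1.23e-05, 0.00225, 0.000751, 0.00225, 0.0293 and 0.00118, and adjusted p = 0.094, 0.094, 0.115, 0.094, 0.436 and 0.115 with an estimated correlation). With 1 library left out the senescence, epithelial and blood lists lost their call in at least 1 fit (adjusted p of up to 0.381, 0.418 and 0.0667). Adjusted over the list alone, 10 imprinted genes, 8 neuronal, 6 muscle, 3 blood, 3 epithelial and 2 endothelial markers, 5 germline and 5 senescence genes, 3 protocadherin genes and 1 Hox gene rose.

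Interferon-stimulated genes had a median of -0.97 in the combined group (-0.78 and -1.37 within the sets, 0 of 56 passing, adjusted p = 2e-09, and adjusted p = 0.435 with an estimated correlation). With the block 15 of them fell, among them Ifit3 (-3.08 ± 0.36, adjusted p = 0.00455), and Slfn5 rose (1.21 ± 0.27, adjusted p = 0.0335). Cholesterol synthesis genes had a median of -0.61 (adjusted p = 3.01e-06, and adjusted p = 0.33 with an estimated correlation). With the block 6 fell, among them Hmgcs1, which makes the HMG-CoA of the mevalonate pathway (-0.87 ± 0.17, adjusted p = 0.0219). PRC1, PRC2, perturbed, cell-cycle, p53, stress, ribosomal protein and silencing cofactor lists did not pass (adjusted p of 0.0844 or more). In edgeR with the block, 1377 genes were higher and 315 lower, and DESeq2 called 901 and 126. A fit to only the libraries compared called 1 gene higher and 0 lower. The count of 217 became 1 (BB287469) without the control library of set 20 and 10 without that of set 28. It became 36 and 43 without the inhibitor libraries of sets 20 and 28, and 6 and 6 without the combined libraries. The count of 5 became 1 (Dnajc13) and 2 (Dnajc13 and Il1rl1, both picked after their values were seen) without the inhibitor libraries of sets 20 and 28 and 0 without any of the other 6 libraries.

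The Ring1a knockdown without inhibitor moved no gene past the threshold in edgeR, without or with the replicate block (154 and 564 genes at an unadjusted p under 0.05). Ring1, the target of the shRNA, did not pass either. For this comparison 0% of simulated 2-fold and 14.9% of 4-fold changes were recovered, and 28.4% and 79.1% with the block. The simulation held 67 changed entries of each of these folds, and the shares can be lower where fewer entries change. The absence of calls therefore does not show an absence of change. DESeq2 called 1 gene, Xpo6, lower (-1.24 ± 0.23, adjusted p = 0.000613), and DESeq2 with the block called 16 higher and 15 lower. The genes with the smallest p in edgeR, none of which passed (adjusted p = 1), were Ogfrl1 (0 counts in the control against 0.650 and 1.14 CPM, at least 10.0-fold), Xpo6 (-1.24 ± 0.20, -0.98 and -1.47 within the sets), C1ql1 (a ratio of 13.1, counting interval 4.18 to 65.8) and Usp17ld (a ratio of 6.83, 1.59 to 61.5). Usp17ld passed adjusted over the list alone, the only member of a list to do so in this comparison.

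As groups, cholesterol synthesis genes were lower in the knockdown, with a median of -0.41 (-0.62 and -0.12 within the sets) and 20 of 24 lower in both sets (adjusted p = 1.72e-11, and adjusted p = 0.526 with an estimated correlation). Cell-cycle genes had a median of -0.15 (-0.14 and -0.16, adjusted p = 3.78e-06, and adjusted p = 0.526 with an estimated correlation). Developmental factors were at 0.13 (0.21 and 0.06, adjusted p = 0.00201, and adjusted p = 0.526 with an estimated correlation) and p53 targets and CDK inhibitors at 0.14 (0.15 and 0.12, adjusted p = 0.0439, and adjusted p = 0.526 with an estimated correlation). The other lists did not pass (adjusted p of 0.0701 or more), among them Hox genes (median 0.26, adjusted p = 0.0701), PRC1 subunits (0.12, adjusted p = 0.184) and interferon-stimulated genes (0.13, adjusted p = 0.146). Without the control library of set 28 the interferon list passed in the opposite direction (adjusted p = 0.0344). Without the control library of set 20 the cholesterol and developmental lists lost their call (adjusted p = 0.464 and 0.616), and without that of set 28 the p53 list did (adjusted p = 0.818), while the cell-cycle list passed in every such fit. With the block 7 lists passed in place of 4, and with 1 library left out 3 to 10, 7 without either control library or the knockdown library of set 20 and 10 without the knockdown library of set 28.

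The knockdown with inhibitor, the same knockdown in cells under DS3201, also moved no gene past the threshold in edgeR (266 genes at an unadjusted p under 0.05, 1101 with the block). Here 0% of simulated 2-fold and 14.9% of 4-fold changes were recovered, and 38.8% and 76.1% with the block. These shares too can be lower where fewer entries change than in the simulation. The smallest p belonged to 4 genes that did not pass (adjusted p = 1): Xpo6 (-1.17 ± 0.20), Mbnl3 (-1.37 ± 0.25), Epb4.1, a membrane skeleton protein (-1.01 ± 0.20), and Dnajc13, an endosomal cochaperone (-1.22 ± 0.24). DESeq2 called these 4 and Ppp2ca, a catalytic subunit of protein phosphatase 2A, lower (adjusted p from 0.00636 to 0.0478), and with the block 9 higher and 26 lower. Developmental factors had a median of 0.37 (0.46 in each set, adjusted p = 6.27e-07) and Hox genes of 0.48 (0.48 and 0.46, adjusted p = 0.00838), and both gave adjusted p = 0.659 with an estimated correlation.

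Interferon-stimulated genes were at -0.65 in that comparison (-0.76 and -0.25, adjusted p = 6.87e-07), cell-cycle genes at -0.22 (adjusted p = 0.000321), ribosomal protein genes at 0.19 (adjusted p = 7.38e-05) and silencing cofactors at -0.22 (-0.01 and -0.35, adjusted p = 0.013), each with adjusted p = 0.659 with an estimated correlation. The interferon direction turned without the inhibitor library of set 20 (adjusted p = 0.15) and without the combined library of set 28 (adjusted p = 0.682). No other list passed (adjusted p of 0.0982 or more), and without the inhibitor library of set 28 the protocadherin beta cluster turned direction and passed (adjusted p = 0.85 with all libraries and 0.0275 without it). Without the inhibitor library of set 20 the count of 6 lists became 2, with the developmental and Hox lists among those lost (adjusted p = 0.317 and 0.611). Of the 6 lists, only ribosomal protein genes passed in every fit with 1 library left out. The knockdown's log2 fold changes with and without inhibitor had Pearson's r of 0.314 and Spearman's rho of 0.352 across 14393 genes.

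Repeat subfamilies were counted in the same libraries and made up 8.65% and 9.72% of counts in the control and 8.59% and 9.92% in the knockdown (sets 20 and 28). The shares were 10.4% and 14.6% in the inhibitor group and 10.8% and 12.95% in the combined group. With DS3201 and control shRNA 2 of 894 subfamilies rose, ERVB4_3-I_MM-int of the ERVK family (2.67 ± 0.34, 2.90 and 2.33 within the sets, adjusted p = 0.0425) and RLTR1B-int of ERV1 (1.56 ± 0.18, adjusted p = 0.0296). MERVL-int, the retrovirus of 2-cell embryos, went from 201 and 264 CPM to 930 and 2194 CPM (2.75 ± 0.55, adjusted p = 0.107). It rose with the block (2.62, adjusted p = 0.00332), as did its promoter MT2_Mm (adjusted p = 0.126 without and 0.00868 with the block). IAPEz-int, the most counted subfamily named here, was at 34340 and 39490 CPM in the control and 40320 and 56800 CPM with DS3201 (0.40 ± 0.30, adjusted p = 0.654). With the block 30 subfamilies rose. The count of 2 was 0 without any library other than the inhibitor library of set 20, without which 2 others passed, ETnERV2-int and RMER17B, both picked after their values were seen.

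Young L1 subfamilies were high in 1 library. L1Md_T was at 6929 CPM in the inhibitor library of set 28 and from 1165 to 2775 CPM in the other libraries, and L1Md_A at 2247 CPM against 587 to 831 CPM. Within the sets, the log2 fold change of L1Md_T with DS3201 was 0.15 and 1.42, and that of the major satellite GSAT_MM was -1.45 and 1.12. As families, L1 (median 0.73, 0.16 and 1.08 within the sets, adjusted p = 4.45e-06), ERVK (0.63, 0.30 and 0.79, adjusted p = 1.1e-05), ERV1 (0.64, 0.29 and 0.82, adjusted p = 0.000205), ERVL-MaLR (0.46, 0.25 and 0.67, adjusted p = 0.00038) and ERVL (0.52, 0.31 and 0.66, adjusted p = 0.0134) were higher with DS3201, each with adjusted p = 0.758 with an estimated correlation. The IAP set was at 0.49 (0.43 and 0.44, adjusted p = 0.0687), and the remaining 11 families did not pass (adjusted p of 0.108 or more).

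In the combined group against control, ERVB4_3-I_MM-int rose (2.83 ± 0.34, adjusted p = 0.0287), and with the block MERVL-int (adjusted p = 0.0759 without and 0.00239 with it) and MT2_Mm (adjusted p = 0.0692 and 0.00366) rose as well. The call of ERVB4_3-I_MM-int was lost without any control, inhibitor or combined library. No subfamily passed with DS3201 in the knockdown cells, where MERVL-int was at 2.97 (adjusted p = 0.0985) and passed with the block (adjusted p = 0.0023), 1 of 12 called with it. edgeR called 0 there against 31 subfamilies at an unadjusted p under 0.05, and DESeq2 called 8. No repeat family passed in these comparisons, the smallest adjusted p being 0.174 and 0.252. In the knockdown without inhibitor no subfamily or family passed (0 subfamilies at an unadjusted p under 0.05, smallest family adjusted p = 0.0901), and DESeq2 with the block called 1, MURVY-int (0.93 ± 0.19), picked after its value was seen.

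With inhibitor the knockdown had repeat medians that differed between the sets. The median over all 894 subfamilies was -0.25, with 0.08 in set 20 and -0.52 in set 28. L1 (-0.51, 0.09 and -0.89, adjusted p = 7.03e-16), ERVK (-0.27, 0.04 and -0.51, adjusted p = 9.29e-06), ERVL-MaLR (-0.24, adjusted p = 9.45e-06), ERV1 (-0.16, adjusted p = 0.0217), ERVL (-0.18, adjusted p = 0.0264) and TcMar-Tigger (-0.23, adjusted p = 0.0296) passed downward, each with adjusted p = 0.657 with an estimated correlation. In set 20 all 6 of these families had a median above 0. No subfamily passed (6 at an unadjusted p under 0.05).

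**Figure D4:**
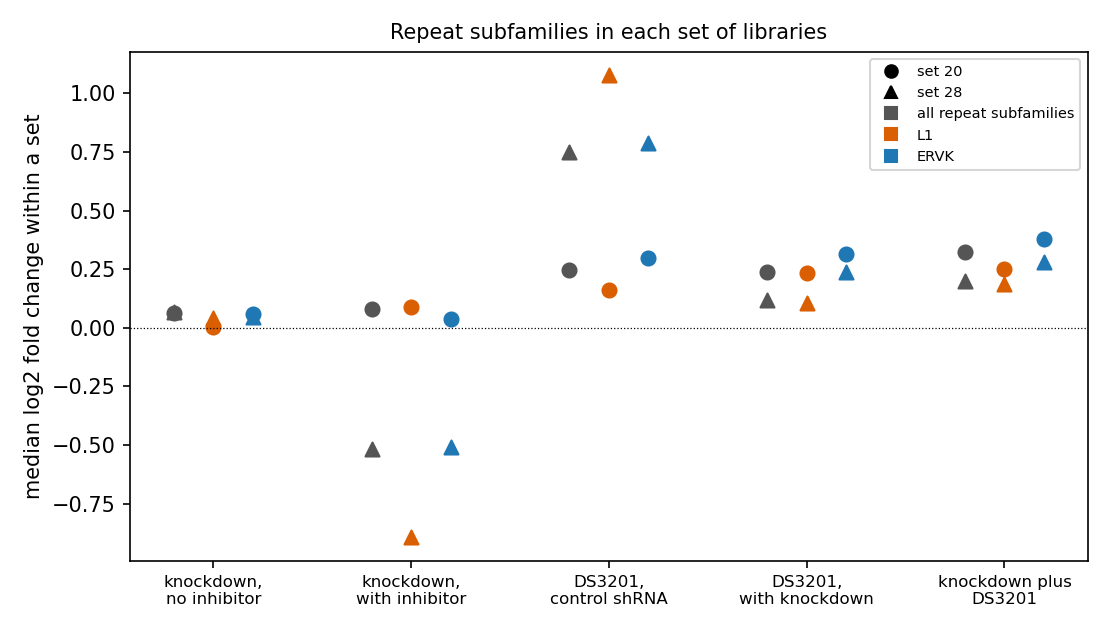
Median log2 fold change of all repeat subfamilies, L1 and ERVK within set 20 and within set 28 for the 5 comparisons between groups, where each circle (set 20) or triangle (set 28) is the median over the subfamilies. For DS3201 with control shRNA the L1 median was 0.16 in set 20 and 1.08 in set 28.

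The interaction, which tests whether the effect of the knockdown differs under DS3201, passed for no gene or subfamily in edgeR or DESeq2 (19 genes at an unadjusted p under 0.05, 132 with the block). On simulated data the fit without the block recovered 0% of 4-fold and 42.4% of 16-fold interactions, so most differences of these sizes would not have been called. With the block it was 4.48% of 2-fold, 53.7% of 4-fold and 84.8% of 16-fold interactions. Most 2-fold differences would thus not have been called with it, and the shares can be lower where fewer entries change than in the simulation. The smallest p belonged to Ogfrl1, Usp17ld (-2.37 ± 0.55), Sema6a and Vmn2r3 (5.38 ± 1.89), none of which passed (adjusted p = 1). Interferon-stimulated genes had an interaction median of -0.80 (-0.81 and -0.67 within the sets, 43 of 56 negative in both, adjusted p = 1.3e-10, and adjusted p = 0.966 with an estimated correlation). It turned direction without the inhibitor library of set 20 (adjusted p = 0.27). Ribosomal protein genes (0.22, 0.06 and 0.39, adjusted p = 4.66e-08), cholesterol synthesis genes (0.31, 0.32 and 0.32, adjusted p = 6.41e-05) and silencing cofactors (-0.25, -0.04 and -0.45, adjusted p = 0.00197) also passed, each with adjusted p = 0.959 with an estimated correlation. With 1 library left out these 3 lost their call in at least 1 fit, with adjusted p of up to 0.198, 0.978 and 0.318. The other lists did not pass (adjusted p of 0.219 or more), developmental factors (0.07, adjusted p = 0.471) and 2-cell embryo genes (-0.17, adjusted p = 0.927) among them. Cell-cycle genes (adjusted p = 0.927) turned direction and passed without the inhibitor library of set 28 (adjusted p = 0.0348). The count of 4 lists ranged from 2 without the inhibitor library of set 20 to 7 without the knockdown library of set 20.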

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

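The correlations with gene span and with span over transcript length were not set in advance. No other test in this part was chosen after its result was seen, but the library that the tests of repeats examine was. Each result below was singled out because the effect of the knockdown differed between cells with and without DS3201 by the interaction test on a list. None of them passed with an estimated correlation, where the adjusted p values were 0.535 to 0.586 for repeat families, 0.966 for interferon-stimulated genes and 0.959 for the other gene lists.

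Among repeat families the interaction medians were negative. L1 had a median of -0.55 (adjusted p = 6.25e-17), ERVK -0.33 (adjusted p = 3.77e-07), ERVL-MaLR -0.26 (adjusted p = 5.4e-07), ERV1 -0.38 (adjusted p = 6.5e-06) and ERVL -0.24 (adjusted p = 0.00266). DNA transposon families and Alu followed: hAT-Blackjack -0.63 (adjusted p = 0.00093), DNA -0.93 (adjusted p = 0.0151), TcMar-Tigger -0.31 (adjusted p = 0.0151), TcMar-Tc2 -0.97 (adjusted p = 0.0213), hAT-Charlie -0.24 (adjusted p = 0.0296) and Alu -0.21 (adjusted p = 0.0151).

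Interferon-stimulated genes had an interaction median of -0.80 (adjusted p = 1.3e-10), with -0.81 in set 20 and -0.67 in set 28. Ribosomal protein genes had a median of 0.22 (adjusted p = 4.66e-08), with 0.06 and 0.39 within the sets. Cholesterol synthesis genes had a median of 0.31 (adjusted p = 6.41e-05), with 0.32 in each set. The silencing cofactors of transposable elements had a median of -0.25 (adjusted p = 0.00197), with -0.04 and -0.45 within the sets. With 1 library left out each of these 4 lists lost its call in at least 1 fit, with adjusted p of up to 0.839, 0.198, 0.978 and 0.318 in the same order.

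The repeat families were highest in the inhibitor library of set 28, and the interaction of L1 was 0.07 in set 20 and -0.98 in set 28. In that library the extra log2 deviation had a median of 0.88 for L1, 0.52 for ERVK and 0.51 for all repeat subfamilies, against -0.03 for genes. Unspliced RNA in that library was a candidate explanation. The test took 103 subfamilies of the old families MIR, L2, hAT-Charlie and TcMar-Tigger to lie mostly in introns, which was not measured. Their pooled median extra deviation was 0.41 (quartiles 0.06 and 0.68), above the bound of 0.3. It was 0.40 for hAT-Charlie, 0.45 for TcMar-Tigger and 0.64 for L2 but 0.15 for the 4 subfamilies of MIR. The test cannot decide, since the library was picked for its high repeats and the pooled median lay below that of all subfamilies (0.51). Of the 103, 58 were hAT-Charlie and 37 TcMar-Tigger, families whose interactions had been flagged. A bias by transcript length and a change of the RNA itself cannot be told apart, since Spearman's rho of a gene's extra deviation with transcript length was 0.18 over 11316 genes, between the bounds of 0.1 and 0.2 set in advance, and rho with gene span (0.284) and with span over transcript length (0.252), for which no bound was set, was larger. The labels set replicates apart only by a batch that all 4 groups share, and the extra deviation is taken after the mean difference between the sets in the other 3 groups, so an effect of batch on this library alone stays open and no biological explanation was tested.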

How the results depend on the processing

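DESeq2 with the replicate block, the replicate block without the inhibitor library of set 28, the replicate block with an estimated correlation and library sizes from genes alone were chosen after the data were seen. Genes and subfamilies named here for small counts were picked after their values were seen. With 1 library left out, the lone library of a group is assumed to vary like those of the other groups. Depth limited the genes with 0 counts in a group, whose folds are lower bounds. On simulated data the fit without the block recovered 0% of 2-fold changes, so smaller changes were not detectable with it. Where a value below moved, the cause was not tested, except that a fit to the compared libraries alone and each fit with 1 library left out have fewer samples. All genes called in edgeR in a comparison were also called with the replicate block and with DESeq2.

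With the replicate block, genes higher and lower were 982 and 108 for DS3201 with control shRNA (30 repeat subfamilies higher), 1377 and 315 for the combined group (31 higher) and 913 and 126 for DS3201 with the knockdown (12 higher), and 7 lists passed for the knockdown. DESeq2 gave 708 and 67 (23 subfamilies higher), 901 and 126 (17) and 612 and 38 (8) for the same 3 comparisons, 1 gene lower for the knockdown without and 5 with inhibitor. DESeq2 with the block gave 1279 and 422 (75), 1600 and 588 (47) and 1121 and 324 (23), 16 and 15 for the knockdown without inhibitor (1 subfamily higher), and 9 and 26 with it.

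With the replicate block and without the inhibitor library of set 28, genes higher and lower were 596 and 154 for DS3201 with control shRNA, 1983 and 1568 for the combined group and 1160 and 861 for DS3201 with the knockdown. Subfamilies higher and lower were 19 and 3 (MurERV4-int, GSAT_MM and RLTR45-int), 91 and 10, and 42 and 3 (MurERV4-int, RLTR21 and GSAT_MM). There GSAT_MM reversed with DS3201 and control shRNA, from 1.08 to -1.64 (adjusted p = 0.0469).

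With the library total alone, DS3201 with control shRNA had 58 genes and 1 subfamily higher (RLTR1B-int), and the combined group 143 genes higher and 3 lower (Dnajc13, Mbnl3 and Etnk1). With no filter on low counts, DS3201 with control shRNA had 188 genes higher and 1 lower (Pdgfrb), DS3201 with the knockdown 209 higher and 1 lower (Pdgfrb) with 1 subfamily higher (ERVB4_3-I_MM-int), the combined group 2 subfamilies higher (MT2_Mm and ERVB4_3-I_MM-int), and the knockdown 2 lists. Without that filter, Pearson's r and Spearman's rho across genes were 0.0607 and 0.206 for the knockdown effect and 0.727 and 0.624 for the inhibitor effect. With at least 10 counts in 4 libraries, DS3201 with the knockdown had 139 genes and 1 subfamily higher (ERVB4_3-I_MM-int). With only the libraries compared, DS3201 with control shRNA had 0 genes and 0 subfamilies higher, the combined group 1 gene higher (BB287469), 0 lower and 0 subfamilies, and DS3201 with the knockdown 2 genes higher (Usp17lb and BB287469).

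With an estimated correlation, lists called fell from 4 to 0 for the knockdown, 13 to 1 for DS3201 with control shRNA, 15 to 1 for the combined group, 6 to 0 for the knockdown with inhibitor, 12 to 1 for DS3201 with the knockdown and 4 to 0 for the interaction. With the block and an estimated correlation they were 0, 1, 2, 0, 1 and 0.

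With each library left out in turn, genes higher ranged from 1 to 89 for DS3201 with control shRNA (109 with all), from 1 to 189 for the combined group (217) and from 1 to 91 for DS3201 with the knockdown (92). Genes lower in the combined group ranged from 0 to 2 (5). Subfamilies higher ranged from 0 to 2 for DS3201 with control shRNA (2) and from 0 to 1 for the combined group (1). Lists called ranged from 3 to 10 for the knockdown (4), from 2 to 7 with inhibitor (6) and from 2 to 7 for the interaction (4). The adjusted p of the interferon list ranged from 2.58e-06 to 0.496 for the knockdown (reversed at 0.0344 without the control library of set 28), from 3.84e-09 to 0.269 for DS3201 with control shRNA (reversed at 0.268 without the inhibitor library of set 28), from 1.52e-38 to 0.682 for the knockdown with inhibitor (reversed at 0.15 without the inhibitor library of set 20 and at 0.682 without the combined library of set 28) and from 3.9e-47 to 0.839 for the interaction (reversed at 0.27 without the inhibitor library of set 20). Without the inhibitor library of set 28, the protocadherin list of the knockdown with inhibitor reversed at 0.0275 (range 0.0221 to 0.806) and the cell-cycle list of the interaction at 0.0348 (range 0.0348 to 0.953). Other called lists lost their call in at least 1 such fit, with these highest adjusted p values. For the knockdown they were cholesterol synthesis (0.464), developmental factors (0.616) and p53 targets (0.818), and with inhibitor Hox genes (0.611), developmental factors (0.317), cell-cycle genes (0.457) and silencing cofactors (0.446). For DS3201 with control shRNA they were endothelial (0.278), blood (0.174) and muscle markers (0.0538) and ribosomal protein genes (0.928), and with the knockdown cholesterol synthesis (0.105). For the combined group they were Hox genes (0.32), senescence secretory genes (0.381), epithelial (0.418) and blood markers (0.0667), and for the interaction cholesterol synthesis (0.978), ribosomal protein genes (0.198) and silencing cofactors (0.318). Pearson's r ranged from 0.103 to 0.257 for the knockdown effect (0.314 with all) and from 0.818 to 0.907 for the inhibitor effect (0.934), and Spearman's rho from 0.182 to 0.312 (0.352) and from 0.561 to 0.699 (0.729).

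Named genes and repeats were counted once per comparison that names them. Of these results, 221 kept their side of the threshold and direction with RLE size factors, 219 with library sizes from genes alone, 219 with at least 10 counts in 4 libraries and 216 with no filter. With the block 209 did and 9 more passed, and with DESeq2 208 did and 13 more passed. With the library total alone 15 no longer passed, and with only the libraries compared 65. Over the fits with 1 library left out, 1225 values kept their side, 390 no longer passed, and 161 that passed in neither fit changed sign. Of the list results 135 kept their side with RLE size factors, 134 with the library total alone and 129 with the block, and 51 no longer passed with an estimated correlation. With the block 4 more list results passed and 2 no longer did.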

Other observations

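The tests of the 2-cell embryo genes and of X-linked genes were chosen after the result was seen. The genes named in this part outside the lists were picked after their values were seen.

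The MHC class II gene H2-Aa rose with DS3201, and 2 neighbours on chr17 rose only with the replicate block. No list of these genes was fixed in advance or tested. H2-Aa (34282744 to 34287823) was at 0 counts in the control and knockdown and at 7.81 and 13.2 CPM in the inhibitor and combined groups. H2-Ab1 (34257689 to 34269419) was at 0 counts without DS3201 and at 1.38 and 2.02 CPM with it, (adjusted p = 0.0858 and 0.0597 against control without and 0.0208 and 0.0113 with the block). H2-Eb1 (34305867 to 34316674) was at 0.0671 CPM in the control and 2.13 and 2.47 CPM with DS3201 (adjusted p = 0.184 and 0.138 without and 0.0472 and 0.0288 with the block). Cd74, which encodes their invariant chain, did not pass (0.45 ± 1.99 without and 0.41 ± 0.37 with the block) and differed between the sets, at 18.9 and 0.738 CPM in the control.

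The 5 genes that DESeq2 called lower in the knockdown with inhibitor had lower group means with the Ring1a shRNA in both arms, but none of them passed in edgeR in either arm, without or with the block. DESeq2 called Xpo6 in both arms and Dnajc13, Mbnl3, Epb4.1 and Ppp2ca only with inhibitor. Xpo6 (chr7, 126101715 to 126200501) was at 68.9 and 89.3 CPM in the control, 34.9 and 32.2 CPM in the knockdown, 74.1 and 77.6 CPM in the inhibitor group and 34.4 and 32.9 CPM in the combined group. Group means of Dnajc13 were 293, 133, 279 and 120 CPM in the same order, those of Mbnl3 101, 48.4, 85.0 and 32.9 CPM, those of Epb4.1 78.85, 46.3, 102 and 50.6 CPM, and those of Ppp2ca 315, 163, 349 and 172 CPM. The labels name no other hairpin against Ring1a, so an effect of this hairpin on other transcripts was not tested.

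The 2-cell embryo genes had medians above 0 with DS3201 in both sets and both arms. MERVL-int was also higher but passed only with the block (adjusted p = 0.107 and 0.0985 without it in the control and knockdown cells). Dux, the homeobox factor that activates MERVL and Zscan4, had group means of 0.0908 and 0.702 CPM without and with DS3201 in the control cells and 0.135 and 2.34 CPM in the knockdown cells. It did not pass with the control shRNA, and passed only with the block in the knockdown cells (4.36 ± 1.15, adjusted p = 0.257 without and 0.0471 with it) and in the combined group against control (4.68 ± 1.29, adjusted p = 0.163 without and 0.0315 with it).

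Reads shared between paralogs were weighed for the 2-cell embryo genes, since the rule for such reads is not given. The inhibitor library of set 28 was not the whole of it, since the list median in set 20 was 5.14. The 6 members that share under 5% of their 50-base words with other genes (Zfp352, Prame, Spz1, Tmem92, Arg2 and Nelfa) had median log2 fold changes of 2.78 and 3.08 within the sets and 3.58 with the 4 members at 0 control counts set to their bound, with 0 called without and 4 with the block. Their lower quartile within a set was 1.45, under the bound of 2. Arg2 and Nelfa, which share 0% of their words, moved least (0.94 and 0.04 log2 in set 28). Zfp352, Prame, Spz1 and Tmem92 share 4.58%, 1.54%, 0% and 0.79% and rose from 0 control counts. Of these, Zfp352 reached 8.02 CPM, but Prame, Tmem92 and Spz1 only 0.963, 0.995 and 1.197 CPM. So for the 6 members the test did not tell reads shared between paralogs from transcripts of each member. The same holds for the 18 other members, which share a median of 45% of their words, between the bounds of 10% and 95%.

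X-linked gene entries under 1 CPM in the control, tested or not, were called higher with DS3201 in the fit with the replicate block more often than autosomal ones, at 60 of 571 (10.5%) against 660 of 10592 (6.23%), an odds ratio of 1.77 (95% limits 1.34 and 2.34, two-sided Fisher's exact test p = 0.000153). Without the block the odds ratio was 1.04 (0.422 and 2.58). The highest autosome was chr4 at 9.97%, and in the combined group against control chr4 was above the X, at 12.9% against 11.6% (odds ratio of the X 1.41 with and 0.743 without the block). For DS3201 with the knockdown the X was at 9.61% with the block, autosomes at 6.24% and chr4, the highest, at 9.28%. The odds ratio there was 1.6 (1.19 and 2.14) with and 1.29 (0.52 and 3.21) without the block. The tables argue against a lower control level as the whole of it, with an odds ratio over 4 bins of control level of 1.92 (1.45 and 2.55), and against reads shared between paralogs, with 1.65 (1.18 and 2.32) among entries sharing under 5% of their words, though the limits of the latter held 1 in the combined group (1.35, 0.978 and 1.86) and without the block (1.74, 0.695 and 4.34, and 1.16, 0.537 and 2.49 in the combined group). Neighbouring genes are not independent and chr4 came close or above, so no explanation particular to the X is offered.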
